A study of Mus musculus with 11 samples.

How the data were processed

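RNA of newborn ovaries from wild-type (n = 4), Sohlh1 KO (n = 4) and Sohlh2 KO (n = 3) mice had been hybridized to Illumina MouseWG-6 v2 BeadChips, 1 array per sample, after DNase treatment and biotin labelling of cRNA. Per the submitters' processing notes the arrays were read with BeadStudio 3.2. The deposited intensity table held linear intensity values without detection p values or control probes, and which step made them is not stated. Its values were not background-subtracted (lowest 98.39, median 152, highest 33822 on every array), and they were already quantile normalized, since arrays differed by at most 11.2 intensity units at the same rank, although the table is described as non-normalized. The deposited series matrix held log2 values equal to the log2 of the same intensity to within 0.005. Replicate numbers were taken from the sample titles, and groups from the titles and descriptions.

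The design had assumed detection p values, which the deposited table lacks. In their place the 1276 probes of olfactory receptor genes served as negative controls. This choice was made after the file was opened. Background was corrected with the normexp model (offset 16) of limma 3.58.1 in R 4.3.3 with statmod 1.5.0, followed by quantile normalization and log2. A probe counted as above background on an array when it exceeded the 95th percentile of the olfactory receptor probes of that array, a level of 149.3 to 158.9 on the intensity scale. Probes above it on at least 3 arrays were kept (24451 of 45281). Signal over background sets what can be seen: 48.7% to 52.6% of probes were above it in wild type, 46.9% to 49.3% in Sohlh1 KO and 45.2% to 48.1% in Sohlh2 KO. Of all probes, 34885 had 1 gene symbol, 18 had several and 10378 had none. Symbols were compared through the Entrez identifiers of 34807 probes with a current gene table, which changed 0 of them. Each gene was represented by its kept probe with the highest mean, which left 13350 genes, 5169 of them with several kept probes. Arrays of a group correlated at 0.969 to 0.992 across the tested genes.

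A linear model of 3 group means was fitted to all 11 arrays (8 residual degrees of freedom) with limma, and moderated statistics were adjusted by the Benjamini-Hochberg method over the genes of each comparison, with calls at an adjusted p under 0.05. The comparisons were each knockout against wild type and Sohlh1 KO against Sohlh2 KO. The gene lists (18 tested, and a list of Y-linked genes with 1 measured member, which was not tested) were compared with all other genes by camera with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists, and fry was run beside it. Fry tests a list without comparing it with other genes. Set tests below are those of camera unless fry is named. Overlap of the knockouts was compared with simulated unchanged groups and with wild-type arrays split between the comparisons. Groups, comparisons, lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Sohlh1 and Sohlh2, the 12 largest falls and 10 largest rises among called genes whose groups did not overlap, up to 4 members of each list with the smallest adjusted p, and up to 10 called genes of the direct comparison. Genes whose probe was above background on 0 arrays of a group are given as a bound, with that group's values raised to the background level.

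In simulated data with 200 changed genes, a log2 change of 1 was recovered for 70.1% of genes in Sohlh1 KO against wild type and 71.6% in the other comparisons, and a change of 0.5 for 16.4%, 13.4% and 20.9%. A raised list was called and 0 of 50 unchanged lists were. The genes were simulated without correlation between them, so this does not test the preset correlation on real lists. Alternatives were no background correction, the series matrix values, median scaling, cyclic loess, no filter or a strict filter (99th percentile) on dim probes, all probes, array weights, replicate number or chip as a block, only the groups compared, each array left out, wild type 2 and 3 left out (their titles carry a letter b whose meaning is not given), and a 2-fold minimum. Added after the data were seen were an offset of 50, another background level, chip as a random block, each chip alone and the lists without blood precursor genes. In the direct comparison of the knockouts, alternatives were followed for the 5 lists and 5 genes called there and for the targeted genes, a limit set after alternatives had been seen to turn several uncalled lists. Probes without a gene symbol were left out of all comparisons. The medians of all genes were 0.035 and 0.044 in the knockouts against wild type and -0.016 between them, and no scaling moved these by more than 0.1. That is no test of a shift shared by most genes. Every alternative started from values that were already quantile normalized, so such a shift could not be seen under any of them.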

Results

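Transcript levels were measured on Illumina MouseWG-6 v2 BeadChips in total RNA from newborn mouse ovaries of a C57BL/6/129S6/SvEv background. Sohlh1 and Sohlh2 encode basic helix-loop-helix transcription factors of germ cells. The 11 arrays came from wild-type ovaries (n = 4), Sohlh1 knockout ovaries (Sohlh1 KO, n = 4) and Sohlh2 knockout ovaries (Sohlh2 KO, n = 3), and the labels do not say whether replicates were separate animals. The arrays lay on 2 chips: chip 1 held the 4 wild-type arrays and Sohlh1 KO 1 and 2, and chip 2 held Sohlh1 KO 3 and 4 and the 3 Sohlh2 KO arrays. Between 45.2% and 52.6% of the 45281 probes were above background on each array, and 13350 genes were tested. Precision was limited by the number of arrays. All values below are normalized log2 values, and an error after ± is the SD over the arrays of a group.

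The targeted genes were read first, as a check of the labels. Sohlh1 was at 11.26 ± 0.15 (SD, n = 4) in wild type, 8.70 ± 0.29 (SD, n = 4) in Sohlh1 KO and 8.70 ± 0.11 (SD, n = 3) in Sohlh2 KO. It thus fell in both knockouts, 5.94-fold in Sohlh1 KO (log2 difference -2.57, SE 0.148, adjusted p = 2.72e-08) and 5.9-fold in Sohlh2 KO (-2.56, SE 0.16, adjusted p = 7.43e-08). With chip as a block the differences were -2.81 and -3.04. The Sohlh2 probe was faint. It rose 1.62-fold in Sohlh1 KO, from 5.01 ± 0.14 (SD, n = 4) to 5.71 ± 0.44 (SD, n = 4), with an adjusted p = 0.0115 (log2 difference 0.696), and 0.989 with chip as a block (adjusted p = 0.00168). This call ended without background correction (0.204, adjusted p = 0.0526) and when wild type 2 and 3 were left out (0.631, adjusted p = 0.103). In Sohlh2 KO the Sohlh2 probe was at 4.70 ± 0.06 (SD, n = 3), above background on 0 of 3 arrays, and its difference from wild type did not pass (-0.312, adjusted p = 0.284, and 0.274 in the opposite direction with chip as a block). Whether the probes lie in the deleted parts of the genes is not known from the labels. As a check, the Sohlh1 values set both knockouts apart from wild type. Neither gene gave a called difference between the knockouts in the main fit, so the check does not tell these 2 labels apart.

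**Figure D1:**
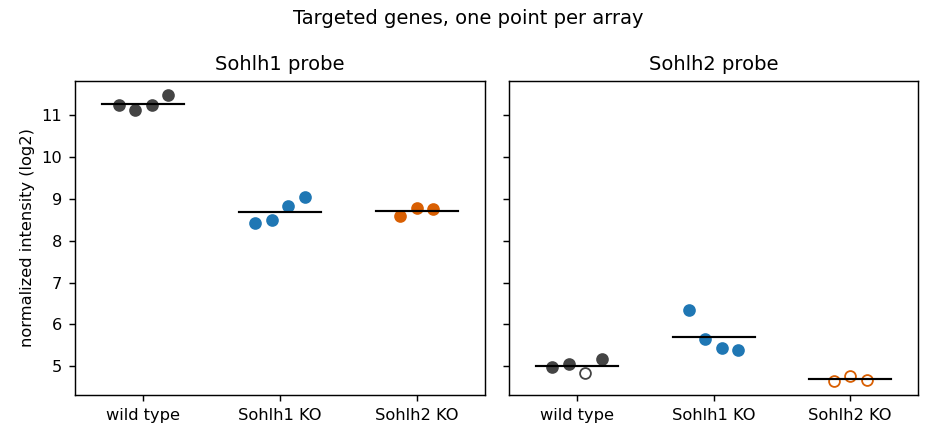
Normalized log2 value of the probe used for Sohlh1 and for Sohlh2 on each of the 11 arrays, by group, with the group mean as a bar and open circles for values not above background. The Sohlh1 probe has means of 11.26 in wild type, 8.695 in Sohlh1 KO and 8.703 in Sohlh2 KO.

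The first comparison asked which transcripts change in the newborn ovary when Sohlh1 is missing. Genes of the growing oocyte stood among the largest falls. Nlrp14, an oocyte NLR family gene, fell 147-fold, from 13.92 ± 0.28 (SD, n = 4) to 6.72 ± 0.18 (SD, n = 4). Gdf9, the oocyte growth factor that acts on granulosa cells, fell 70.0-fold, from 13.43 ± 0.16 to 7.30 ± 0.10 (SD, n = 4 each; adjusted p = 1.97e-11). Zp3, a protein of the zona pellucida, fell 63.5-fold, from 12.44 ± 0.24 to 6.45 ± 0.41 (SD, n = 4 each). The secreted oocyte protein Oosp1 was at least 78.5-fold lower, and the oocyte genes E330034G19Rik and Rfpl4 at least 56.2-fold and 42.6-fold. Elobl was at least 74.6-fold lower, 3300002A11Rik at least 43.4-fold and Pramel25 at least 42.4-fold, and Fbxw15 fell 67.2-fold. The largest fitted fall was that of Fam183b, a gene of motile cilia, at least 139-fold lower (12.23 ± 0.28 to 4.60 ± 0.17, SD, n = 4 each). Since this is a bound, whether Fam183b fell more than Nlrp14 cannot be told. Fam166c was at least 35.4-fold lower. Among 19 measured genes of multiciliated cells, a list put together after values were seen, 18 fell (median log2 difference -2.58), and Ccno, which drives centriole amplification in these cells, fell 33.7-fold.

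Of 27 measured maternal-effect and oocyte cytoplasm genes, 25 fell and 1 rose (26 and 1 when adjusted over the list alone). Their median log2 difference was -3.07, or -2.77 with 7 genes at their bound, and the list passed the set test with the preset correlation (adjusted p = 5.75e-25) and with an estimated correlation (adjusted p = 0.00303). Npm2, the oocyte nucleoplasmin, was at least 38.3-fold lower. Of 12 zona pellucida and oocyte secreted or surface proteins, 10 fell and 0 rose (median -2.71, or -2.49 with 2 genes at their bound; adjusted p = 5.79e-13, and 0.00303 as the adjusted p with an estimated correlation). Bmp15, a growth factor related to Gdf9, fell 21.3-fold and Zp1 fell 45.9-fold. Of 15 oocyte transcription regulators, 6 fell and 3 rose (median -0.242, and -0.0939 without wild type 4; mean -1.13). The list passed with the preset correlation (adjusted p = 0.00894) but not with the estimated one (adjusted p = 0.151 with an estimated correlation). Pou5f1, a transcription factor of pluripotent cells and oocytes, fell 7.59-fold, Sall4 fell 11.9-fold, Obox5 was at least 13.7-fold lower and Obox1 at least 10.3-fold.

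Genes of early germ cells and of meiosis moved the other way. Of 21 measured genes of meiotic prophase, 14 rose and 2 fell (16 and 3 over the list alone), with a median log2 difference of 1.11. Syce3, a synaptonemal complex protein, rose 34.9-fold, from 5.59 ± 1.06 to 10.71 ± 0.32 (SD, n = 4 each). Stag3, a meiotic cohesin, rose 6.16-fold, Meiob, which acts in meiotic recombination, 5.73-fold and Sycp2, of the synaptonemal complex, 5.49-fold. Of 24 germ cell identity and piRNA pathway genes, 15 rose and 4 fell, with a median of 0.733. Tex101, a germ cell surface protein, rose 8.02-fold (4.87 ± 0.20 to 7.87 ± 0.18, SD, n = 4 each), Asz1, of the piRNA pathway, 3.37-fold and Tex19.1 2.75-fold, while Sohlh1 itself, a member of this list, fell. Both lists passed with the preset correlation (adjusted p = 3.6e-06 for meiotic prophase and 0.000993 for germ cell identity). With an estimated correlation neither did (adjusted p = 0.101 and adjusted p = 0.294 with an estimated correlation). The largest rise of any gene was that of Taf7l, a germ cell paralog of a TFIID subunit, 109-fold, from 5.79 ± 1.8 to 12.57 ± 0.42 (SD, n = 4 each). Its log2 difference was 6.77, and 7.67 without wild type 4, the array on which it was highest in that group. Gm773 rose 48.5-fold, Tktl1 35.2-fold and Cabs1 35.0-fold.

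Among genes of somatic ovarian cells, those of steroid synthesis fell. Of 9 steroidogenic and theca cell genes, 7 fell and 0 rose (median log2 difference -1.36; adjusted p = 9.39e-06, and 0.00687 as the adjusted p with an estimated correlation). Cyp17a1, the enzyme of androgen synthesis, fell 26.6-fold, from 10.45 ± 0.48 to 5.71 ± 0.84 (SD, n = 4 each). Hsd3b1 fell 7.36-fold, and the hedgehog targets Hhip and Ptch1 fell 3.75-fold and 2.56-fold. Of 22 pregranulosa and granulosa cell genes, 9 fell and 7 rose. The median of that list was 0.207, its mean -0.536, and its set test, directed down, did not pass (adjusted p = 0.494). By fry the list passed downward (adjusted p = 8.63e-06). Its strongest members all fell: Hsd17b1, an enzyme of estrogen synthesis, 24.4-fold (12.15 ± 0.24 to 7.54 ± 0.43, SD, n = 4 each), Inha, a subunit of inhibin, 9.67-fold, the estrogen receptor Esr2 5.39-fold and the receptor for follicle-stimulating hormone Fshr at least 12.4-fold. Of 11 Sertoli and testis genes, 3 fell and 2 rose (adjusted p = 0.426; median -0.262, -0.0358 without Sohlh1 KO 4 and 0.0591 with chip as a block). This list too passed downward by fry (adjusted p = 0.00423). Dhh fell 5.36-fold and Amh, a hormone of granulosa and Sertoli cells, was at least 2.74-fold lower. Alongside these groups, 7 of 8 genes whose transcripts decline after birth, a list written after the main results were seen, rose (median 1.41). Among them were the imprinted growth genes Igf2 and Peg3, named here after their values were seen.

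Markers of other tissues and of blood moved as well. Of 10 smooth muscle and pericyte genes, 7 fell and 1 rose (median log2 difference -0.867; adjusted p = 0.000229, and adjusted p = 0.117 with an estimated correlation). Actg2, an actin of visceral smooth muscle, fell 11.2-fold and Myh11, a smooth muscle myosin, 6.85-fold. Of 8 fat tissue genes, 5 fell and 1 rose (median -0.687; adjusted p = 0.00252, and adjusted p = 0.0942 with an estimated correlation), with the adipocyte hormone Adipoq down 48.1-fold (10.52 ± 0.43 to 4.93 ± 0.30, SD, n = 4 each) and Cidea at least 7.21-fold lower. Of 8 red blood cell genes, 6 rose and 1 fell (median 1.64; adjusted p = 0.000153, and adjusted p = 0.124 with an estimated correlation). The globin gene Hba-a1 rose 3.45-fold, Alas2, an enzyme of heme synthesis in red cells, 12.9-fold and the red cell anion exchanger Slc4a1 31.9-fold (5.83 ± 0.35 to 10.82 ± 2.36, SD, n = 4 each). Myeloid genes stood among the largest rises: Stfa1 rose 44.5-fold, Cstdc4 40.1-fold and the neutrophil proteins S100a9 41.2-fold and S100a8 34.0-fold. Sohlh1 KO 1 was the lowest of its group for these genes. Without it the log2 differences moved from 5.36 to 5.99 for S100a9, from 5.09 to 5.69 for S100a8, from 5.32 to 5.92 for Cstdc4 and from 5.0 to 6.13 for Slc4a1, and without Sohlh1 KO 4 that of Slc4a1 was 4.36.

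For the other 7 tested lists the set test by camera did not pass. By fry, 2 of them passed upward: p53 and apoptosis (adjusted p = 0.00643) and KIT and PI3K signalling (adjusted p = 0.00608). Endothelial genes went both ways, 4 up and 3 down (adjusted p = 0.649), with Pecam1, an adhesion molecule of these cells, up 1.96-fold and the transcription factor Sox17 down 3.00-fold. So did genes of the surface and ductal epithelium (2 up and 4 down; adjusted p = 0.396), where Krt14 rose 4.84-fold and Cldn3, a tight junction protein, fell 3.11-fold. Of 20 proliferation genes 2 rose and 5 fell (adjusted p = 0.494), with Aurka, a mitotic kinase, down 2.32-fold. Of 17 p53 and apoptosis genes 3 rose and 2 fell (adjusted p = 0.427). The p53 target and cell cycle inhibitor Cdkn1a was among those that fell (log2 difference -0.826). Without wild type 2 and 3 it lost its call (-0.709, adjusted p = 0.0677), as did Apaf1, Zmat3 and Sesn1 of that list (adjusted p = 0.0601, 0.0583 and 0.0963). Of 13 genes of KIT and PI3K signalling 4 rose and 0 fell (adjusted p = 0.223). The rise of Rictor among them (0.281) was lost whichever 1 array was left out and with chip as a block (adjusted p = 0.0618), and that of Foxo3 without wild type 2 and 3 (adjusted p = 0.0918). Cdkn1b, another cell cycle inhibitor, rose 2.02-fold. Its call rests on 1 of its 2 probes, since the other did not pass (0.39, adjusted p = 0.219), and 1 of 2 other probes did not pass for Cdkn1a (0.0301) and for Pecam1 (0.461). Of 13 stress and immediate early genes 4 rose and 2 fell (adjusted p = 0.174). Of 16 macrophage and leukocyte genes 4 rose and 1 fell (adjusted p = 0.272, but 0.0177 without wild type 1). In that last list Cd14 fell 2.14-fold and Mrc1 rose 1.76-fold. The rises of the stress genes Fos and Atf3 and of the leukocyte genes Tyrobp and Laptm5 were lost with chip as a block (adjusted p = 0.075, 0.0895, 0.128 and 0.138).

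In all, 4366 genes were called in Sohlh1 KO against wild type at an adjusted p under 0.05, 2173 higher and 2193 lower. At least 2-fold changes were seen for 493 higher and 912 lower genes. With chip as a block 3588 genes were called, and all 4366 kept their sign. Within chip 1, with 4 wild-type and 2 Sohlh1 KO arrays, 2988 were called and all 4366 kept their sign. This is no second check of sign or size. Only Sohlh1 KO lay on both chips, so the blocked log2 differences equal those within chip 1. Only their spread was estimated in another way. Of the 18 lists, 9 passed with the preset correlation, 3 with an estimated one and 9 with chip as a block. The size of a change in a faint gene depended on the background correction: without it the fitted log2 difference of Fam183b was -5.17 in place of -7.62, that of Tex101 1.27 in place of 3.00 and that of Fshr -1.93 in place of -3.96, each still past the threshold. The fitted values of Fam183b and Fshr, which are given as bounds above, are no measured sizes.

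**Figure D2:**
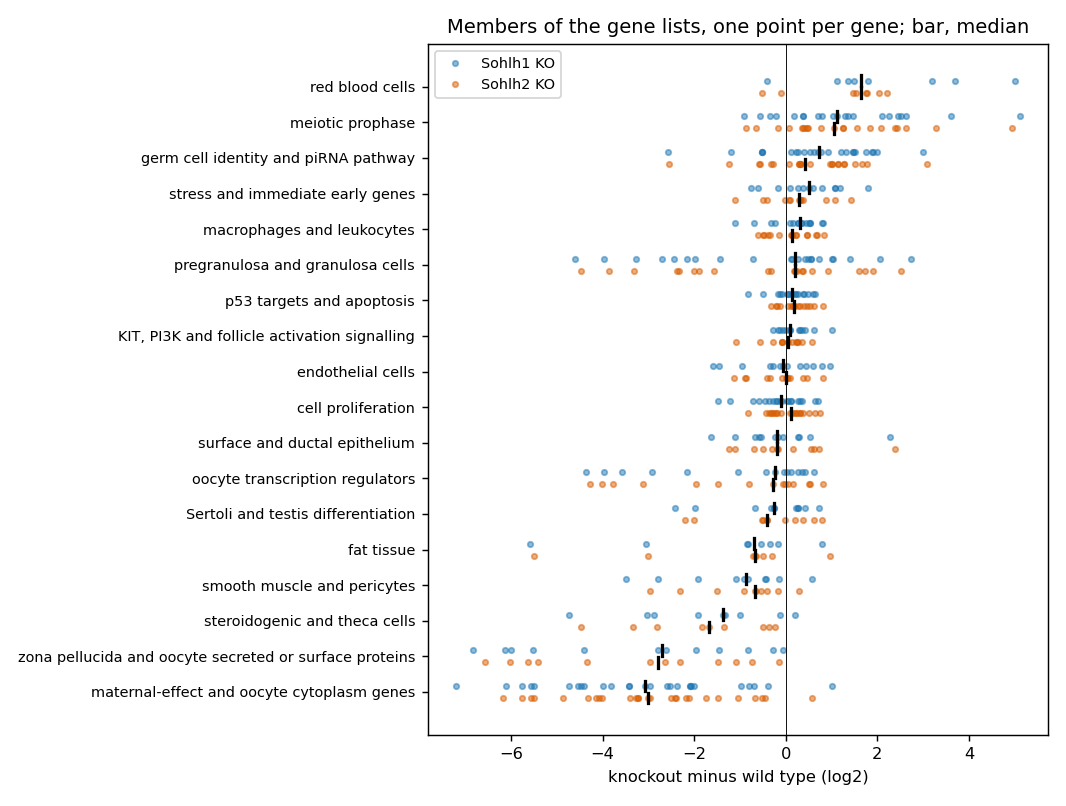
Log2 difference from wild type of each measured member of the gene lists (points) in Sohlh1 KO and in Sohlh2 KO, with the list's median as a black bar. The maternal-effect and oocyte cytoplasm genes have medians of -3.07 and -3.0, and the meiotic prophase genes 1.11 and 1.05.

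The second comparison asked the same of the ovary without Sohlh2. Oocyte genes again stood among the largest falls. Nlrp14 fell 72.2-fold, to 7.75 ± 0.31 (SD, n = 3). Gdf9 fell 65.3-fold, to 7.40 ± 0.41 (SD, n = 3; adjusted p = 6.86e-11), Zp3 49.2-fold, to 6.82 ± 0.44 (SD, n = 3), Oosp1 94.3-fold, Fbxw15 65.4-fold and E330034G19Rik 53.9-fold. Elobl was at least 72.9-fold lower, 3300002A11Rik at least 42.4-fold and Pramel25 at least 41.4-fold. Fam183b was at least 136-fold lower, at 4.61 ± 0.14 (SD, n = 3), and of the 19 genes of multiciliated cells 16 fell (median log2 difference -2.66), with Ccno down 25.4-fold. That median is the fitted value of Ccdc39, which was at least 4.34-fold lower. Its probe was above background on 0 Sohlh2 KO arrays, so the median is no measured size. Fam166c and the lipid transfer family gene Sec14l3 were at least 34.6-fold and 32.1-fold lower.

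Of the 27 maternal-effect and oocyte cytoplasm genes, 26 fell and 1 rose in Sohlh2 KO (median log2 difference -3.0, or -2.73 with 6 genes at their bound). Npm2 fell 45.0-fold and Rfpl4 was at least 41.6-fold lower. Of the 12 zona pellucida and oocyte secreted or surface proteins, 11 fell and 0 rose (median -2.80, or -2.63 with 2 genes at their bound), with Bmp15 down 20.4-fold and Zp1 42.6-fold. Both lists passed with the preset correlation (adjusted p = 9.4e-28 and 3.39e-16) and with an estimated one (adjusted p = 0.00166 for each). Of the 15 oocyte transcription regulators, 7 fell and 2 rose (3 rose over the list alone; median -0.268, and -0.121 without wild type 4; adjusted p = 0.00174, and adjusted p = 0.101 with an estimated correlation). Pou5f1 fell 8.66-fold and Sall4 13.8-fold, and Obox5 was at least 13.4-fold lower.

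Of the 21 meiotic prophase genes, 12 rose and 1 fell in Sohlh2 KO (15 and 2 over the list alone), with a median log2 difference of 1.05. Syce3 rose 30.4-fold, to 10.51 ± 0.06 (SD, n = 3), Stag3 6.14-fold, Meiob 5.38-fold and Sycp2 5.25-fold. Of the 24 germ cell identity and piRNA pathway genes, 10 rose and 3 fell (12 and 4 over the list alone; median 0.430). Tex101 rose 8.51-fold, Asz1 3.19-fold and Tdrkh, a Tudor protein of the piRNA pathway, 2.02-fold. These lists passed with the preset correlation (adjusted p = 1.22e-06 and 0.0118). With an estimated correlation they did not (adjusted p = 0.0893 and adjusted p = 0.406 with an estimated correlation). Taf7l rose 89.6-fold, to 12.28 ± 0.15 (SD, n = 3), and its log2 difference of 6.49 became 7.38 without wild type 4. Gm773 rose 41.9-fold, Tktl1 32.9-fold, the X-linked homeobox gene Rhox13 32.0-fold, Cabs1 29.1-fold and Sis, an intestinal disaccharidase, 20.6-fold. Dmrtc1c1 rose 15.5-fold and 1700080O16Rik 13.7-fold, and Dmrtc2, a germ cell transcription factor, was at least 12-fold higher.

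Steroidogenic and theca cell genes fell in Sohlh2 KO: 6 of 9 fell and 0 rose (7 fell over the list alone; median log2 difference -1.68; adjusted p = 9.6e-07, and 0.00366 as the adjusted p with an estimated correlation). Cyp17a1 fell 22.3-fold, to 5.97 ± 0.16 (SD, n = 3), Insl3, a peptide hormone of theca and Leydig cells, 10.1-fold and Hsd3b1 7.02-fold. Of the 22 pregranulosa and granulosa cell genes, 8 fell and 6 rose (median 0.191, and 0.0917 without Sohlh2 KO 4, mean -0.535, test directed down, adjusted p = 0.376). By fry the list passed downward (adjusted p = 4.11e-05). Hsd17b1 fell 22.2-fold, Fshr 14.4-fold and Inha 9.97-fold, while Lgr5, a marker of ovarian surface and pregranulosa cells, rose 3.00-fold. In this comparison too, 7 of the 8 genes whose transcripts decline after birth rose (median 1.24). Smooth muscle and pericyte genes fell (6 of 10, with 0 up; median -0.668; adjusted p = 0.00029, and adjusted p = 0.101 with an estimated correlation), among them Actg2 7.79-fold and Myh11 4.94-fold. Of the 8 fat tissue genes, 5 fell and 1 rose (median -0.662; adjusted p = 0.00113, and adjusted p = 0.0632 with an estimated correlation). Adipoq was at least 41.5-fold lower, and Cidea fell 8.05-fold. Of the 8 red blood cell genes, 5 rose and 1 fell (median 1.65; adjusted p = 0.00293, and adjusted p = 0.235 with an estimated correlation). Hba-a1 rose 3.39-fold and Alas2 4.63-fold. That list no longer passed with chip as a block (median 1.35, adjusted p = 0.0517).

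The set tests of the other 8 lists by camera did not pass in Sohlh2 KO. By fry, p53 and apoptosis genes passed upward (adjusted p = 0.000237) and Sertoli and testis genes downward (adjusted p = 0.008). In the KIT and PI3K list 1 gene rose and 1 fell (adjusted p = 0.803; median 0.0483, mean -0.0244). The gene that fell was Kit, the receptor tyrosine kinase of oocytes and primordial germ cells, 2.13-fold, from 10.49 ± 0.06 (SD, n = 4) to 9.40 ± 0.18 (SD, n = 3), with an adjusted p = 0.000983, though with chip as a block its log2 difference went from -1.09 to -0.506 and did not pass (adjusted p = 0.221). Endothelial genes had 1 up and 3 down (adjusted p = 0.508; median 0.0154, and -0.0685 without Sohlh2 KO 3, mean -0.145), with Pecam1 up 1.75-fold by the probe used and Sox17 down 2.19-fold. Epithelial genes had 4 up and 3 down (adjusted p = 0.734; median -0.184, from -0.323 to -0.063 with 1 array left out, mean 0.0207), with Cdh1, the epithelial cadherin, down 2.14-fold. Other probes of these genes did not pass (0.0278 and 0.423 for Pecam1, -0.388 for Cdh1). Sertoli genes had 2 up and 4 down (adjusted p = 0.328), with Dhh down 4.62-fold and Amh at least 2.67-fold lower. Counts up and down were 4 and 0 for p53 and apoptosis (adjusted p = 0.209), 2 and 1 for proliferation (adjusted p = 0.784), 2 and 1 for macrophages and leukocytes (adjusted p = 0.633) and 1 and 1 for stress genes (adjusted p = 0.552). With chip as a block the 4 p53 and apoptosis rises (adjusted p from 0.0727 to 0.731), the rises of the proliferation genes Mcm3 and Ccne1 (0.22 and 0.388) and of the macrophage genes Mrc1 and C1qb (0.0583 and 0.492) and the stress gene calls, Jun and Hspa1b (0.509 and 0.192), were lost. So were the rise of Mtor in the KIT and PI3K list, that of Krt14 in the epithelial list and the calls of Fgf9 and Aard in the Sertoli list.

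In all, 3405 genes were called in Sohlh2 KO against wild type, 1671 higher and 1734 lower, of which 392 higher and 821 lower genes changed at least 2-fold. No Sohlh2 KO array shared a chip with a wild-type array, so no within-chip value can be had. With chip as a block, through the Sohlh1 KO arrays on both chips, 1712 genes were called, 676 higher and 1036 lower. Of the 3405 genes, 3386 kept their sign under the block and 1491 stayed called, and the median SE of a log2 difference went from 0.173 to 0.273. Of the 18 lists, 9 passed with the preset correlation, 3 with an estimated one and 8 with chip as a block. With wild type 2 and 3 left out 1870 genes were called.

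The third comparison asked how far the changes in the knockouts were shared. Of the genes called in each, 2900 had changed the same way, 1365 up and 1535 down, and 2 in opposite ways. The shared falls took in Nlrp14, Gdf9, Zp3, Bmp15, Npm2, Cyp17a1 and Hsd17b1, and the shared rises Taf7l, Gm773, Syce3, Stag3 and Tex101. The shared genes were 85.2% of the Sohlh2 KO calls, against 556.8 genes for lists drawn independently. Across genes, which are not independent replicates, the correlation of the log2 differences was 0.936, where 100 simulated pairs of unchanged groups against the same wild-type arrays gave 0.464 on average and 0.493 at most. With the wild-type arrays split between the comparisons, 1766 to 1882 genes changed the same way and the correlation was 0.883 to 0.904. With chip as a block 1604 genes did. Genes called in Sohlh1 KO alone numbered 1464, and in Sohlh2 KO alone 503. Whether these differ between the knockouts is a question for the direct comparison, and a gene not called there may still differ. In simulated data that comparison recovered 20.9% of log2 changes of 0.5.

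**Figure D3:**
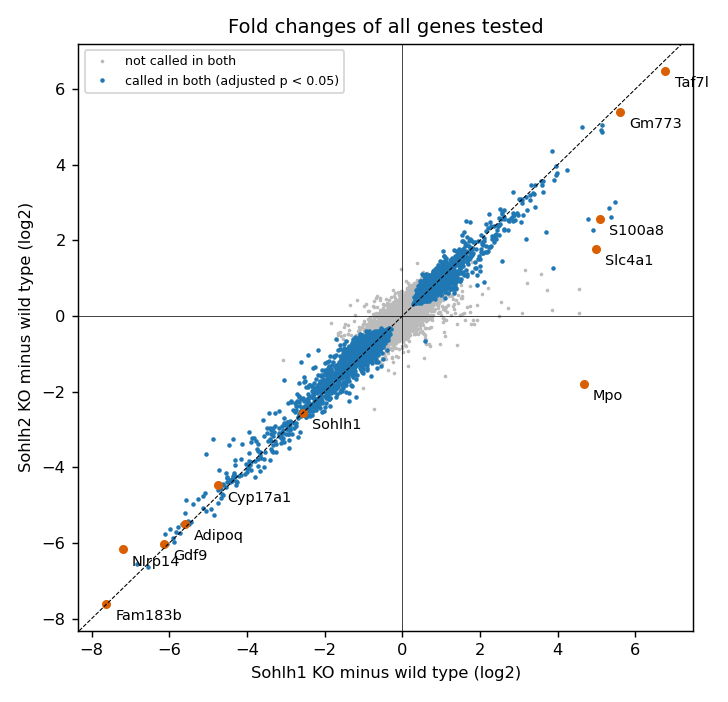
Log2 difference from wild type in Sohlh1 KO (horizontal axis) and Sohlh2 KO (vertical axis) for each of the 13350 genes, with genes called in both in blue, labelled genes in orange and a dashed line of equal change. Most called genes lie along the line (correlation 0.936), and Mpo lies far below it.

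The direct comparison asked which transcripts differ between the knockouts. It called 5 genes, 4 higher and 1 lower in Sohlh1 KO, and 1136 had an unadjusted p under 0.05. Mpo, myeloperoxidase of granulocytes, was at least 58.7-fold higher in Sohlh1 KO, at 11.02 ± 1.56 (SD, n = 4) against 4.55 ± 0.03 (SD, n = 3, its probe above background on 0 arrays), with wild type at 6.34 ± 0.30 (SD, n = 4). Ctsg, a granule protease of the same cells, was 14.3-fold higher, at 9.17 ± 1.25 (SD, n = 4) against 5.34 ± 0.56 (SD, n = 3). Srgn, the proteoglycan of secretory granules, was 2.37-fold higher (log2 difference 1.25), Unc13d, which acts in granule release, 1.83-fold higher (0.871) and Efcab11 1.81-fold lower (-0.855). Against wild type, Srgn was at 0.594 in Sohlh1 KO and -0.653 in Sohlh2 KO. Unc13d was at 0.0889 and -0.782 by the probe used, so its difference came from a fall in Sohlh2 KO. Efcab11 was lower in both (-1.61 and -0.755). The call of Unc13d rests on 1 of its 2 probes, since the other was at 0.0334 (adjusted p = 0.99). The other probes of Srgn (0.919, adjusted p = 0.0821) and Efcab11 (-0.639 and -0.393, adjusted p = 0.438 and 0.634) did not pass. Of the 3 other Mpo probes 1 passed (5.07, adjusted p = 0.011), and 2 did not (3.19 and 1.99, adjusted p = 0.0821 and 0.182). Adjusted p values were 0.0011 for Mpo, 0.0205 for Ctsg, 0.0154 for Srgn, 0.021 for Unc13d and 0.0421 for Efcab11. With chip as a block they were 1.79e-07, 1.65e-05, 0.0322, 0.00932 and 0.0573, and within chip 2 the adjusted p was 4.82e-06 for Mpo, 0.0102 for Ctsg, 0.114 for Srgn, 0.0841 for Unc13d and 0.19 for Efcab11. The log2 differences with chip as a block equal those within chip 2, so the block and chip 2 are not separate checks of them. Calls numbered 26 with chip as a block, 21 within chip 2, 1 without background correction (Srgn), 69 without Sohlh1 KO 1, 1 without Sohlh1 KO 3 and 2 without the blood precursor genes. The blood precursor genes left out included Mpo and Ctsg themselves. Mpo stayed called whichever 1 array was left out, and the other 4 genes did not. Without background correction Mpo lost its call too (log2 difference 4.06, adjusted p = 0.0531), as with the series matrix values (4.06, adjusted p = 0.0523), so the size given above depends on that correction. Srgn lost its call without Sohlh1 KO 3 (adjusted p = 0.0616) and without Sohlh2 KO 4 (adjusted p = 0.0854). Ctsg lost its call without wild type 1, 2 or 3, Sohlh1 KO 3, or Sohlh2 KO 2 or 4 (adjusted p from 0.0504 to 0.0857). Unc13d kept it only without Sohlh1 KO 1 or 2, and Efcab11 only without Sohlh1 KO 1 (adjusted p otherwise 0.0516 to 0.101 and 0.0528 to 0.171). The level of Sohlh1 did not differ (log2 difference -0.00828, adjusted p = 0.997), and that of Sohlh2, above background on 0 of 3 Sohlh2 KO arrays, did not pass (at least 1.48-fold, adjusted p = 0.081).

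Of the gene lists, 5 passed in the direct comparison with the preset correlation and 0 with an estimated one. Red blood cell genes were higher in Sohlh1 KO (median log2 difference 0.625, adjusted p = 0.00508, and adjusted p = 0.478 with an estimated correlation; 0.474 with chip as a block). That call was lost without Sohlh2 KO 2 (0.310, adjusted p = 0.0842) and when blood precursor genes were left out (0.0226, adjusted p = 0.445). The genes left out included Slc4a1, Alas2 and Rhag of this same list (log2 differences 3.22, 1.48 and 1.22). The second loss was thus to be foreseen and is no independent test. Maternal-effect and oocyte cytoplasm genes were lower in Sohlh1 KO by a small margin (median -0.157, adjusted p = 0.00508, and adjusted p = 0.478 with an estimated correlation; -0.195 with chip as a block). This call ended without background correction (-0.0725, adjusted p = 0.0509) and with the series matrix values (-0.0723, adjusted p = 0.0519). For KIT and PI3K genes the median was 0.0717 (adjusted p = 0.0168, and adjusted p = 0.478 with an estimated correlation), for germ cell identity and piRNA genes 0.0775 and for proliferation genes -0.158 (adjusted p = 0.033 for each, and adjusted p = 0.666 with an estimated correlation). These last 3 lists did not pass with chip as a block (adjusted p = 0.0896, 0.811 and 0.951), where the median of the proliferation genes turned to 0.0357. With 1 array left out the medians reached 0.205 for KIT and PI3K genes, 0.0117 to 0.198 for germ cell identity genes and -0.0589 for proliferation genes. Stress and immediate early genes, whose set test did not pass (median 0.205, adjusted p = 0.0771), passed with chip as a block (0.253, adjusted p = 0.016, but 0.774 as the adjusted p with an estimated correlation) and within chip 2 (adjusted p = 0.0443). These 2 results rest on the same log2 differences. Without Sohlh2 KO 2 the KIT and PI3K list (adjusted p = 0.2) and the germ cell list (adjusted p = 0.148) lost their calls, as did the KIT and PI3K list without Sohlh1 KO 2 (adjusted p = 0.0571) and the germ cell list without Sohlh1 KO 1 (adjusted p = 0.506). The proliferation list lost its call without Sohlh1 KO 1, 2 or 3 and without Sohlh2 KO 2 or 4 (adjusted p from 0.0531 to 0.475).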

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

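The chip test of the blood genes and the tests of wild type 4 were chosen after the results were seen. The splits of the arrays were written before. The liver test was written after the main results were seen, but before the values of its genes were. Of 226 groups of 4 arrays over 113 named genes, 10 held an array set apart from the other 3, where chance sets apart about 1 in 20 (11.3 here).

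The direct comparison called Mpo (at least 58.7-fold; fitted log2 difference 6.46, which is no measured size, since its probe was above background on 0 of 3 Sohlh2 KO arrays), Ctsg (log2 difference 3.83), Srgn (1.25), Unc13d (0.871) and Efcab11 (-0.855), and the red blood cell list (0.625). Of 12 granulocyte precursor genes, a list written after the first results, 11 rose in Sohlh1 KO, against 2 up and 1 down in Sohlh2 KO, and the median difference between the knockouts was 2.88; for 9 erythroid precursor genes it was 1.22. Only 2 of the 12 (Mpo and Ctsg) and 0 of the 9 passed the direct comparison, and these lists had no set test. Relative to wild type the granulocyte mean was 1.87, 3.43, 3.98 and 4.89 on the Sohlh1 KO arrays and 0.0535, -0.0193 and 1.27 on the Sohlh2 KO arrays. The erythroid mean was 0.4, 1.88, 1.89 and 3.14 against 0.507, 0.335 and 0.551, so Sohlh1 KO 1 lay within the Sohlh2 KO range.

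Carry-over of newborn liver, a site of blood formation, may be asked about, but the 4 measured liver genes had a median difference of -0.124 between the knockouts, which argues against it. A difference between the chips is argued against by the values within chip 2, where the medians stayed at 3.8 and 1.94. Blood or blood-forming tissue from another source and a biological effect of Sohlh1 loss were not tested and stay open. Of the 35 splits of these 7 arrays into groups of 4 and 3, 3 gave at least 5 genes, so chance is not excluded for this count. The highest other split, with 54 genes, set Sohlh1 KO 1 beside the Sohlh2 KO arrays against Sohlh1 KO 2 to 4, which points to a structure of the samples.

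Over all tested genes wild type 4 lay nearest the knockouts of its group, at -50.72 on the first principal component (67% of the variance). The other wild-type arrays lay at -54.53, -57.85 and -62.94, and the knockout arrays at 27 to 37.21. Wild type 4 had more signal than its group in 4 genes looked at here: Taf7l was at 8.479 there against 4.66 to 5.106 on the other wild-type arrays, Syce3 at 7.171 against 5.01 to 5.097, Tktl1 at 6.704 against a mean of 4.819 and Rhox13 at 5.849 against a mean of 4.716. Knockout RNA mixed into this sample could give such values, but it would give every gene about the same share of the knockout signal, and shares were scattered: 5.75% for Taf7l, 7.07% for Syce3, 0.688% for Gm773, a median of 1.34% over 17 genes near background in the other wild-type arrays, and -7.28% to 17.4% over 21 other genes bright in the knockouts. At the lowest share that Taf7l would need (3.71%), only 3 other genes would have risen beyond the spread of the arrays, and 2 of them (Gm773 and Dmrtc2) stayed short by more than it while Cabs1 did not, which speaks against mixing as the whole source but rests on too few genes to exclude it. This test was the last of 3 tried, its spread and its minimum of 5 genes were set after the values were seen, and the first test, on the genes near background alone, had come out against mixing. A biological difference of this sample was not tested.

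The other arrays set apart were these. Alas2 was at 6.721 in wild type 1 (others 7.043 to 7.103) and C1qb at 8.786 in Sohlh1 KO 1 (others 9.251 to 9.286). Cidea was at 8.407 in wild type 2 (others 7.766 to 7.839) and Cstdc4 at 5.269 in wild type 3 (others 6.102 to 6.217). Sohlh1 KO 4 was set apart in Lmod1 (4.542, others 5.259 to 5.332) and Mcm3 (8.367, others 7.803 to 7.876). Ptgds was at 7.446 in Sohlh1 KO 3 (others 7.017 to 7.08) and Rhox13 at 10.51 in Sohlh1 KO 1 (others 9.22 to 9.407). The other lists that differed between the knockouts were maternal-effect and oocyte cytoplasm genes (median log2 difference -0.157), germ cell identity and piRNA genes (0.0775), proliferation genes (-0.158) and KIT and PI3K genes (0.0717), and 0 of the 5 lists passed with an estimated correlation. Among 3400 kept probes without a gene symbol, which no comparison used, 309 were higher and 311 lower in both knockouts.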

How the results depend on the processing

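Chip alone, chip as a random block, the lists without blood precursor genes, an offset of 50 and another background level were chosen after the results were seen. Of 174 calls of named genes, 132 held under every alternative run for them and 0 reversed; chip as a block ended 25, and leaving out wild type 2 and 3 ended 27 of 169. Calls of gene lists held in 587 runs and were lost in 43, 17 of these with an estimated correlation. Depth is limited by signal over background, since 45.2% to 52.6% of probes were above it. The numbers in the titles did not pair the samples (correlations of same-number arrays from -0.201 to 0.129), and with replicate number as a block the Sohlh1 difference between the knockouts was 0.0423. Where a cause is not given, the cause was not tested.

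Genes changed in Sohlh1 KO against wild type numbered 1405 with a 2-fold minimum, 2540 without wild type 2 and 3 (fewer samples) and 3430 to 4732 with 1 array left out. For Sohlh2 KO they numbered 1213 with the minimum, 1870 without wild type 2 and 3, 5225 with array weights, 1712 with chip as a block (its SE rose) and 2437 to 4129 with 1 array left out. Splits of the arrays argue against chance for both, if the arrays are independent samples, which the labels do not state. Of 35 splits 1 gave 4366 genes (highest other 0), and 1 of 35 gave 3405 (highest other 30). No smaller share can be had from 35 splits. For Sohlh2 KO the real split is also the split between the chips, so it cannot tell genotype from chip. Genes changed the same way in both numbered 1070 with the minimum, 1604 with chip as a block, 1766, 1806, 1873, 1779, 1813 and 1882 with the wild-type arrays split (fewer samples), and 2217 to 3337 with 1 array left out.

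Genes different between the knockouts numbered 3 with the minimum, 1 without background correction and with the series matrix values, 8 with cyclic loess and with the strict filter, 12 over all probes, 45 with array weights, 26 with chip as a block, 2 without blood precursor genes (Mpo and Ctsg among those left out), 1 in a fit of these groups only, 21 on chip 2 only and 1 to 69 with 1 array left out (69 without Sohlh1 KO 1, 1 without Sohlh1 KO 3). Lists past the threshold numbered 3, 3 and 0 with an estimated correlation; 9 to 10, 9 and 1 to 6 with 1 array left out; and, between the knockouts, 3 without background correction, with the series matrix, the strict filter, chip as a block and chip 2 only.

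Sohlh2 in Sohlh1 KO was 0.204 without background correction and with the series matrix, 0.631 without wild type 2 and 3 and 0.482 to 0.805 with 1 array left out. In Sohlh2 KO it was -0.335 with array weights (now past the threshold, adjusted p = 0.0431), 0.274 with chip as a block and -0.371 to -0.26 with 1 array left out, and between the knockouts 0.861 with array weights (adjusted p = 0.0353) and 0.794 to 1.12. The Sohlh2 probe was above background on 0 of 3 Sohlh2 KO arrays, so differences from that group are fitted values and no measured sizes. Sohlh1 was -2.68 to -2.48 and -2.61 to -2.49 in the knockouts with 1 array left out; its difference between them, near 0, turned to 0.0129 with cyclic loess, 0.0487 with array weights, 0.23 with chip as a block and on chip 2 only, 0.0195 with chip as a random block and -0.122 to 0.0799 with 1 array left out. The direction of the set test turned for uncalled lists in Sohlh2 KO (medians in parentheses): with chip as a block proliferation (-0.286), macrophages (0.024) and stress (0.0325); without wild type 2 and 3 macrophages (-0.144) and epithelium (-0.0268); and KIT and PI3K genes without Sohlh2 KO 4 (0.0331; up to 0.0988 with 1 array left out). The macrophage list passed in Sohlh1 KO without wild type 1 (0.488).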

Other observations

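The oviduct and fat tests and the mast cell list were chosen after the results were seen. The test of flanking genes was written before. The stage test was written after the main results were seen, but before the values of its genes were. Genes named in this part were chosen after their values were seen.

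Of 12 measured mast cell genes, a list put together after values were seen, 9 rose and 1 fell in Sohlh1 KO (median log2 difference 2.47), and 8 rose and 2 fell in Sohlh2 KO (median 2.28). The mast cell proteases Cma1, Cpa3, Mcpt4 and Tpsb2 rose by 3.22, 3.11, 2.61 and 3.42 in Sohlh1 KO and by 2.79, 2.67, 2.55 and 2.88 in Sohlh2 KO, and the receptor Mrgprb2 by 2.49 and 2.14. Hdc, the enzyme of histamine synthesis, went the other way (-1.81 and -1.93), as did Kit in Sohlh2 KO (-1.09), while Fcer1a passed in neither knockout and Ms4a2 only in Sohlh1 KO. The list was not compared with other genes by a set test.

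The 8 measured genes that decline after birth, counted in the Results and used in the stage test below, are imprinted and fetal growth genes. In this same list, which had no set test, 7 rose in both knockouts. Igf2 rose by 0.90 and 0.91, Peg3 by 1.46 and 1.53, Cdkn1c by 1.59 and 1.57, Mest by 1.37 and 0.94, Igf2bp1 by 1.74 and 2.04 and Igf2bp3 by 1.79 and 1.63, while Plagl1 did not pass (0.37, adjusted p = 0.0538, and 0.371, adjusted p = 0.0845). Of 2 other probes of Peg3 and 4 of Igf2bp3, 1 each passed in neither knockout (0.576 and 0.799, and 0.357 and 0.333), and 1 of 3 others of Igf2bp1 did not pass in Sohlh1 KO (0.438). A further Igf2bp3 probe did not pass in Sohlh2 KO (0.411, adjusted p = 0.0675). Of 4 measured liver genes 3 fell: Apoa1 by -2.62 and -2.52, Ahsg by -1.43 and -1.36 and Serpina1b by -2.46 and -2.31, although another Serpina1b probe was higher in Sohlh1 KO (0.837, adjusted p = 0.0048) and another Ahsg probe did not pass (-0.236 and -0.282). Apoa2 did not pass (0.0917 and 0.539). Of 8 Y-linked genes only Uty was measured, and it did not pass (-0.31, adjusted p = 0.0787, and -0.286, adjusted p = 0.151).

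Genes of multiciliated cells, the oviduct glycoprotein Ovgp1 and the fat hormone Adipoq were all lower in the knockouts. Of 19 multiciliated cell genes, 18 and 16 fell. Sntn was at least 17-fold and 16.7-fold lower, the regulator Mcidas fell by -2.37 in Sohlh1 KO and was at least 4.36-fold lower in Sohlh2 KO, and Ovgp1 fell from 13.27 ± 0.29 (SD, n = 4) to 9.14 ± 0.14 (SD, n = 4) and 9.89 ± 0.12 (SD, n = 3).

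A candidate explanation is a later developmental stage of the wild-type samples, though all samples are labelled newborn: genes that decline after birth were higher in both knockouts, with a lower median of 1.24. This test could have come out the other way, but it cannot tell stage from changed shares of cell types in the ovary RNA, which could raise the same genes. If the stage did differ, it may also bear on the falls of Gdf9, Zp3, Fshr and Cyp17a1 and on the rises of meiotic genes. There a halt or delay of follicle growth in the knockouts is the biological alternative, which was not tested apart from stage. More oviduct epithelium in the wild-type samples cannot be told apart from these: 7 epithelial genes had medians of -0.23 and -0.199, but all 7 were above background on all 7 knockout arrays, and their own expression in the ovary would hide a share from the oviduct. Fat carried over could likewise not be decided. Of 9 genes of an adipocyte list, 6 fell in both knockouts, among them Plin4 and Cidec, though members of this list need not be confined to fat. Fabp4, among the most abundant adipocyte transcripts, was above background on 3 of 4 wild-type arrays. It did not pass (-0.166, adjusted p = 0.479, and -0.311, adjusted p = 0.229). The limits on Fabp4 and on the background of the epithelial genes were set after those values were seen, and they turned both outcomes: without them the fat test would have come out for carry-over and the oviduct test against more epithelium.

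One further hypothesis was that DNA of another strain flanking the targeted genes could make their neighbours differ between the knockouts. The mean absolute statistic of the 100 measured genes around Sohlh2 lay at the 13.9th percentile of 10993 windows of neighbouring genes. This argues against a broad difference of its neighbours. Around Sohlh1 it lay at the 51.5th percentile, which leaves the question open. A mean over 100 genes could hide a difference in a few close neighbours, so neither value excludes the hypothesis.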
